A study of Homo sapiens with 20 samples.

How the data were processed

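RNA from HCT116 cells, a human colorectal carcinoma line, was measured by RNA sequencing after 5 h or 12 h with 1 of 4 compounds at 500 nM or with DMSO vehicle at 0.5%. The compounds were chaetocin, chetomin and the sulfide-depleted analog of each, which the labels call MeS-chaetocin and MeS-chetomin. Each of the 10 groups held 2 libraries, which the labels call biological replicates, 20 libraries in all, and samples were grouped by the compound and time in their labels. Per the labels, poly(A) RNA libraries were made from 250 ng of RNA with an integrity number of at least 7, using the NEBNext Ultra II Directional kit, with an aim of 50 M reads and 150 cycles. Whether the vehicle and compound libraries of the same number were made together is not given in the sources used here.

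The submitters' processing notes name STAR 2.5.2b for alignment to GRCh38, RSEM 1.3.3 for quantification and edgeR, without a version, for the differential test. The parameters, the gene annotation and the strand setting of the counting step are not given in the sources used here. The 8 deposited tables, 1 per compound and time, hold 1 value per library in normalized signal units, which the file headers do not name as TPM or FPKM. The values follow transcript length and their sum per library ranged from 875371 to 1170802 over the genes listed. Each deposited table also holds a mean CPM per group (signal units), a log2 fold change of compound over vehicle, and a p-value with its Benjamini-Hochberg q-value, whose test the headers do not name. These columns are called the authors' deposited table here; they carry no standard deviation.

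The tables listed 14222 genes at 5 h and 15381 at 12 h, 15531 Ensembl gene IDs in all. Symbols came from a gene-names table for 15423 of the IDs, and positions, gene types, exon counts, lengths and GC content came from GENCODE release 29 (GRCh38) for 15488. IDs without a match kept their Ensembl ID and were tested like the others. A symbol stood on 2 or more IDs in 10 cases; for the gene symbol SDHD the text refers to 1 of 2 entries, ENSG00000255292, whose span also covers neighbouring genes. All 80 per-library columns were used. The vehicle values are repeated in the tables of a time point and were read once.

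The design written before the data were examined assumed read counts and a count model. The deposited values are normalized and not counts, so limma 3.58.1 in R 4.3.3 was fitted to log2(value + 1) with an intensity-dependent prior variance (trend). This change, and everything that follows from it, was made once the type of the values was known; the comparisons, the threshold, the gene lists and the rule for naming genes were made before the data were examined. A log2 difference is therefore one on the log2(value + 1) scale, which understates the change of genes with low values. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in a comparison, with no filter beyond the authors' own; genes with the same value in all libraries fitted were left out. Each of the 8 comparisons with vehicle was fitted on its 4 libraries, each of the 8 direct comparisons of compounds on 6 libraries including vehicle, and each of the 4 comparisons of an effect between 12 h and 5 h, an interaction of compound with time, on 8 libraries. All tests were two-sided. With 2 libraries against 2, an exact two-sided permutation test cannot give a p below 0.333, so the calls rest on limma's pooling of variance over genes.

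Gene lists were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, for lists with at least 3 measured members. There were 27: metallothioneins, zinc transporters, iron and copper handling, heat shock, integrated stress response, endoplasmic reticulum chaperones, NRF2 targets, hypoxia, p53 targets, immediate early genes, ribosome biogenesis, S phase, mitosis, NF-kB targets, interferon response, cholesterol synthesis, apoptosis, Wnt targets, intestinal differentiation, histone acetyltransferases and deacetylases, histone methyltransferases, Integrator, autophagy, proteasome, histones, mitochondrially encoded genes, and markers of other cell types. Members called in a list are counted at the adjusted p over all genes and also adjusted over the list alone. A list's shift is the median log2 difference of its members minus the median of all genes tested.

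The genes named follow a fixed rule: 26 genes always reported; the 10 called genes with the largest change each way against vehicle, or 5 each way in other comparisons, among genes with a mean CPM of at least 5 whose replicates of the 2 groups do not overlap; and up to 4 called members of each list. Some genes this rule gives are not reported here. Genes named outside the rule are stated as chosen after their values were seen. For the overlap of chaetocin and chetomin, which share vehicle libraries, 100 simulations drew groups that share a vehicle and carry no effect. Splitting the vehicle would leave 1 library on each side, so it was not done.

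Depth was recovered from the step size of the authors' mean CPM values, which gave the effective library size for 16 of the 20 libraries, between 21.17 and 39.85 M reads. It was not recovered for the 4 libraries of chaetocin and chetomin at 5 h. An effective size may hold a scaling factor beside the read total. No read counts are at hand, so no counting interval was computed, and the precision given is the spread between libraries.

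The fit was tested on simulated data made from the vehicle means and the fitted spread, in which 100 genes were shifted by each size. At a shift of 1 on the log2 scale the fit recovered 49, 61, 21 and 60 of 100 genes at 5 h for chaetocin, chetomin, MeS-chaetocin and MeS-chetomin. At 12 h it recovered 67, 70, 62 and 72. At a shift of 2 it recovered 100, 100, 89 and 100 at 5 h and 100 in each comparison at 12 h. For chaetocin against chetomin at 12 h it recovered 79 and 100 at shifts of 1 and 2, and for the chaetocin time comparison 18 and 94.

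Alternatives tried were a mean CPM of at least 5, the replicate number as a block, a fit of all libraries of a time point, leaving out each library, an estimated inter-gene correlation and the rotation test fry. Alternatives chosen after the data were seen were the authors' CPM scale (values rescaled so that they follow the authors' mean CPM), median-of-ratios scaling, pseudocounts of 0.1 and 5, a correction for transcript length and GC content, no variance trend, and a crossed pairing of replicates. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and figures.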

Results

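Gene expression was measured in 20 libraries of HCT116 colorectal carcinoma cells, 2 biological replicates for each of 10 groups: DMSO vehicle, chaetocin, chetomin, MeS-chaetocin and MeS-chetomin, each at 5 h and at 12 h. Chaetocin and chetomin are fungal products with disulfide bridges, and the labels call the MeS compounds their sulfide-depleted analogs. The study behind the series concerns chaetocin, the acetyltransferases p300 and CBP, and genes that respond to metals, so the metallothioneins, the zinc exporter SLC30A1, EP300 and CREBBP are given in each comparison with vehicle, called or not. Effective library sizes ran from 21.17 to 39.85 M reads in 16 libraries and were not recovered for the 4 of chaetocin and chetomin at 5 h. The deposited table lists 14222 genes at 5 h and 15381 at 12 h. Vehicle replicate 1 at 5 h stood apart from the other libraries, with 20.29% of its summed values in 10 genes against 9.42% to 17.29% elsewhere.

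Levels are means of the deposited normalized values with their SD (n = 2), and log2 differences are on the log2(value + 1) scale with their SE (limma, 2 libraries per group). With 2 libraries against 2, an exact two-sided permutation test cannot give a p below 0.333, so the calls rest on a spread pooled over genes. The authors' CPM scale moved the median log2 difference of all genes against the deposited scale by 0.16 for chaetocin and 0.16 for chetomin at 5 h, and by 0.28 and 0.24 at 12 h. Shifts of gene lists are therefore given relative to the median of all genes. No gene called against vehicle on both scales changed direction between them.

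Chaetocin at 5 h raised HMOX1 and lowered MYC. HMOX1, the haem-degrading enzyme of the oxidative stress response (ENSG00000100292, GRCh38 chromosome 22, 35380361 to 35394214, 6 exons), rose from 15.9 ± 1.14 to 306 ± 30.7, a log2 difference of 4.18 ± 0.16 (adjusted p 0.000531). MYC, a transcription factor that drives growth (ENSG00000136997, chromosome 8, 127735434 to 127741434, 3 exons), fell from 209 ± 15.2 to 23.1 ± 1.01, a log2 difference of -3.12 ± 0.15 (adjusted p 0.000855). The immediate early transcription factors EGR1 (3.69 ± 0.19), FOSB (3.68 ± 0.27) and NR4A1 (3.51 ± 0.17) rose with them. DKK1, a secreted Wnt antagonist, fell by 3.10 ± 0.20 and SOX4 fell by 2.68 ± 0.21.

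Among metal response genes at 5 h, chaetocin lowered SLC30A1 (ENSG00000170385, chromosome 1, 211571568 to 211578742, 2 exons) from 5.24 ± 1.19 to 1.49 ± 0.361, a log2 difference of -1.32 ± 0.27 (adjusted p 0.0271; 0.127 without chaetocin replicate 1 and 0.222 without replicate 2). The metallothioneins did not pass: MT1X stood at -0.46 (adjusted p 0.136), MT1E at -0.36 (0.348), MT2A at -0.19 and MT1F at 0.08. Their list of 5, which includes SLC30A1, had 1 member called, and did not pass camera (shift -0.27, adjusted p 0.212). Neither EP300 (-0.47, adjusted p 0.441) nor CREBBP (-0.56, adjusted p 0.296) was called. MTF1, the transcription factor of metallothionein genes, was not called at 1.07 (adjusted p 0.0624) on the deposited scale but was on the authors' CPM scale (1.48, adjusted p 0.0216).

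In the heat shock list 11 of 25 members rose with chaetocin at 5 h (14 adjusted over the list alone), among them DNAJB1 (2.76 ± 0.21), HSPA1A (2.49 ± 0.16) and the co-chaperone BAG3 (2.49 ± 0.16). The list shifted by 0.72 (camera adjusted p 2.68e-12, and adjusted p = 0.468 with an estimated correlation). With 4 libraries the estimate leaves next to no power, here and below. Endoplasmic reticulum chaperones had 5 of 18 up (8 adjusted over the list alone), with HERPUD1 at 1.46 ± 0.16 and XBP1 at 1.29 ± 0.16 (shift 0.48, adjusted p 2.91e-05; adjusted p = 0.673 with an estimated correlation). For NRF2 targets 2 of 28 rose, also 2 adjusted over the list alone, namely HMOX1 and MAFG (shift 0.41, adjusted p 5.81e-05; adjusted p = 0.673 with an estimated correlation). SRXN1 (-0.25, adjusted p 0.347) and TXNRD1 (0.60, adjusted p 0.332) were not called. The integrated stress response list had 3 of 23 up, 4 down and no camera call (3 and 7 adjusted over the list alone; shift -0.28, adjusted p 0.112), with DDIT3 at 1.46 ± 0.21, PPP1R15A at 1.21 ± 0.16, CEBPB at -2.67 ± 0.20 and ATF4 at -1.20 ± 0.17. Of 29 immediate early genes 12 rose and 9 fell, or 14 and 10 adjusted over the list alone (shift 0.25, adjusted p 0.0166; adjusted p = 0.726 with an estimated correlation). Of 27 p53 targets 7 fell, or 5 on the authors' CPM scale and 7 adjusted over the list alone. They included PHLDA3 (-1.69 ± 0.23) and the cell cycle inhibitor CDKN1A (-1.12 ± 0.16), and the shift was -0.21 (adjusted p 0.0283; adjusted p = 0.673 with an estimated correlation). Beside these lists, mitochondrially encoded transcripts shifted by 0.64 with 0 of 13 called, also 0 adjusted over the list alone (camera adjusted p 0.000247; adjusted p = 0.746 with an estimated correlation). Without chaetocin replicates 1 and 2 in turn calls ended for MAFG (adjusted p 0.147 and 0.154), ATF4 (0.138 and 0.0701), PPP1R15A (0.0702 and 0.0606), CDKN1A (0.0776 and 0.0861) and PHLDA3 (0.0624 and 0.0595), and without replicate 2 for DDIT3 (0.0631) and XBP1 (0.0517). The markers of other cell types that were measured shifted by 1.53, with the liver gene ALB at 1.44 and the macrophage gene CD68 at 1.74 (adjusted p 0.0263; adjusted p = 0.673 with an estimated correlation). Of 18 such markers 6 were measured at 1 or both times. A marker silent in vehicle is listed only if a treated group is high, so an upward shift is partly built in. This limit holds for these markers in every comparison with vehicle.

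limma called 1576 of 14217 genes with chaetocin at 5 h, 648 up and 928 down, of which 419 and 652 changed by at least 1 on the log2 scale. On the authors' CPM scale 1370 were called, 791 up and 579 down, so that 41.1% of calls were increases on the deposited scale and 57.7% on the authors'. The authors' deposited table calls 4197 genes, 1500 of them also called here in the same direction. Without chaetocin replicate 1 the count was 513 and without chaetocin replicate 2 it was 603, and without vehicle replicate 1 the lists passing camera rose from 7 to 11. Of the 74 named genes called, HMOX1 and MYC kept their calls whichever library was left out, 37 and 38 lost theirs without chaetocin replicates 1 and 2, and 4 without each vehicle replicate.

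With chetomin at 5 h HMOX1 reached 970.2 ± 9.96, a log2 difference from vehicle of 5.85 ± 0.15 (adjusted p 5.07e-06), and NR4A1 reached 566 ± 36.9 from 14.5 ± 0.764 (5.19 ± 0.15, adjusted p 7.05e-06). The long noncoding RNA LINC00659 (ENSG00000228705, chromosome 20, 62774128 to 62775412, annotated as antisense) rose from 2.09 ± 1.51 to 360.3 ± 19.9, a log2 difference of 6.96 ± 0.31 (adjusted p 4.73e-05); the strand used in counting is not given, so its reads are uncertain. DDIT3, a transcription factor of the integrated stress response, rose by 2.57 ± 0.19 and its target TRIB3 by 2.27 ± 0.15. MYC fell to 39 ± 1.15, a log2 difference of -2.39 ± 0.15 (adjusted p 0.000231), and WNT16 fell by 2.57 ± 0.24 (adjusted p 0.000951).

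SLC30A1 fell with chetomin at 5 h to 1.36 ± 0.219 (-1.40 ± 0.25, adjusted p 0.011; 0.186 without chetomin replicate 1 and 0.108 without replicate 2). MT1X (ENSG00000187193, chromosome 16, 56682424 to 56684196) fell from 113 ± 18 to 72.4 ± 5.39, a log2 difference of -0.63 ± 0.17 (adjusted p 0.0446). The call ended on the authors' CPM scale (-0.41, adjusted p 0.278), when all libraries of the time point shared the spread (adjusted p 0.0577) and without chetomin replicate 1 or 2 (0.41 and 0.247). MT1E (-0.40), MT2A (-0.27) and MT1F (-0.08) were not called, and the metallothionein list did not pass (shift -0.32, adjusted p 0.164). EP300 stood at 0 (adjusted p 0.996) and CREBBP at -0.09 (adjusted p 0.852), neither called. MTF1 stood at 0.69 (adjusted p 0.11) and was called on the authors' CPM scale (1.10, adjusted p 0.0159).

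Heat shock genes rose in 12 of 25 cases with chetomin at 5 h (13 adjusted over the list alone), with HSPA1A at 3.54 ± 0.15 and DNAJB1 at 3.87 ± 0.21 (shift 0.71, camera adjusted p 2.9e-12; adjusted p = 0.478 with an estimated correlation). For NRF2 targets 9 of 28 rose (11 adjusted over the list alone), including OSGIN1 (2.08 ± 0.19) and GCLM, a subunit of the enzyme that starts glutathione synthesis (1.78 ± 0.20), with a shift of 0.50 (adjusted p 2.96e-07; adjusted p = 0.478 with an estimated correlation). The integrated stress response list had 11 of 23 up and 1 down, or 13 and 2 adjusted over the list alone, with a shift of 0.60 (adjusted p 9.12e-07; adjusted p = 0.478 with an estimated correlation). Immediate early genes had 16 up and 6 down of 29, or 16 and 9 adjusted over the list alone (shift 1.13, adjusted p 2.91e-05; adjusted p = 0.522 with an estimated correlation). Endoplasmic reticulum chaperones had 4 of 18 up, also 4 adjusted over the list alone (shift 0.36, adjusted p 0.00067; adjusted p = 0.616 with an estimated correlation). Beside these, mitochondrially encoded transcripts shifted by 0.59 with 2 of 13 called, or 4 adjusted over the list alone (adjusted p 0.000838; adjusted p = 0.478 with an estimated correlation). Markers of other cell types shifted by 1.65, with ALB at 1.89 and CD68 at 1.57 (adjusted p 0.00413; adjusted p = 0.478 with an estimated correlation).

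With chetomin at 5 h limma called 2237 of 14219 genes, 998 up and 1239 down. The authors' CPM scale gave 2197, with 1353 up and 844 down, which moved the share of increases from 44.6% to 61.6%, and the authors' deposited table calls 4437. Without chetomin replicate 1 the count was 609 and without chetomin replicate 2 it was 704, and each of these replicates ended the calls of 45 of the 86 named genes, with HMOX1 and MYC kept. Without vehicle replicate 1, 3256 genes were called and 11 lists passed camera in place of 7.

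**Figure D1:**
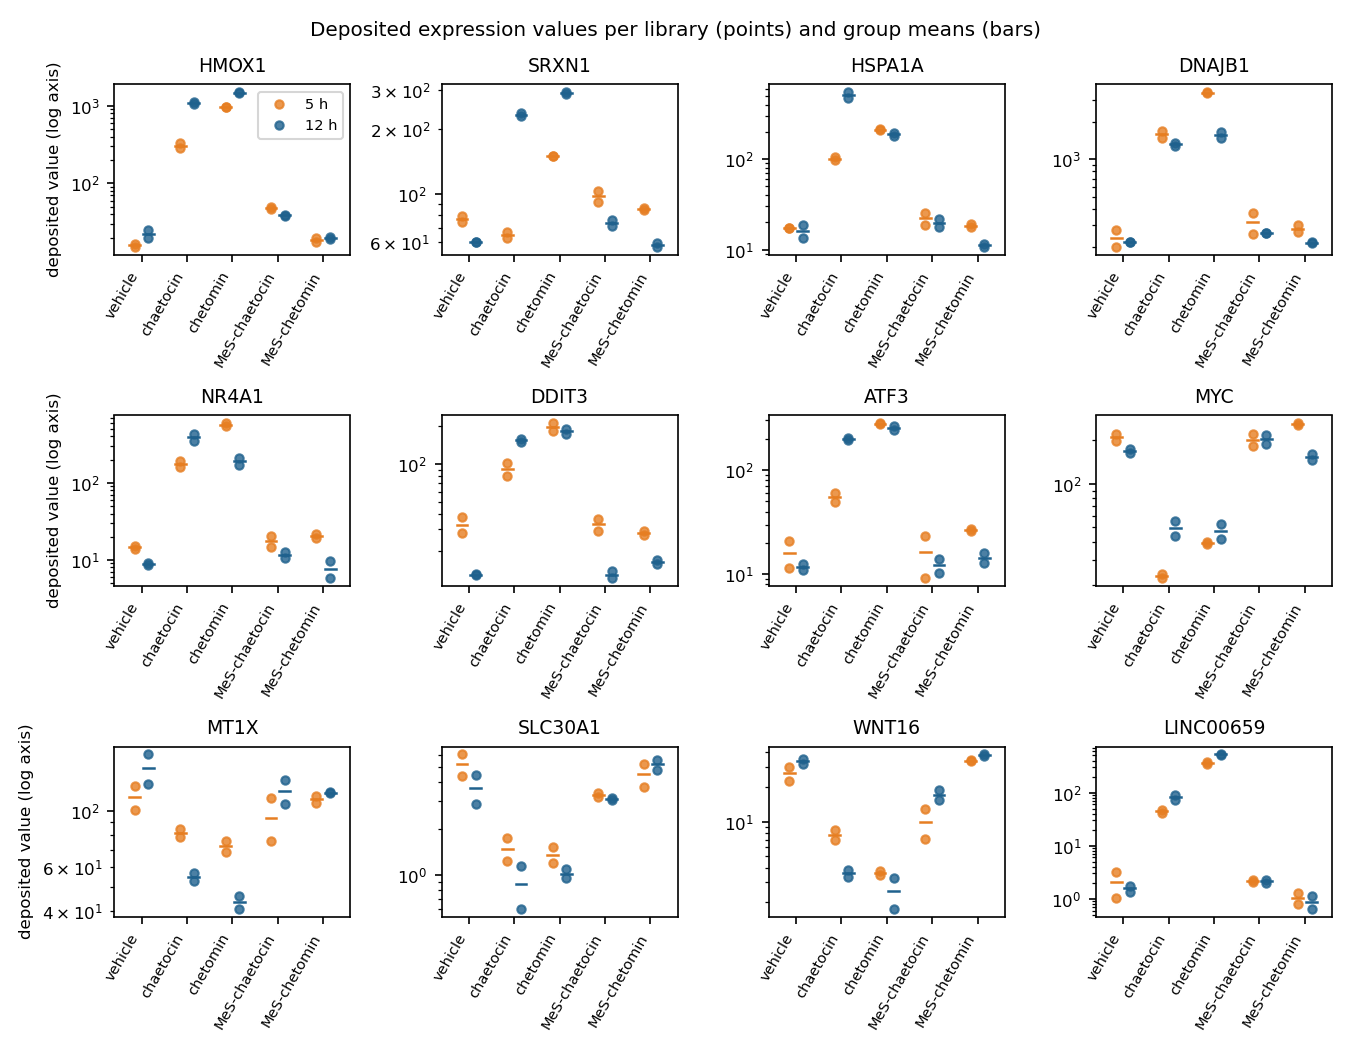
Deposited normalized values of 12 genes in each library (points, log axis) by compound and time, with bars at the means of 2 libraries. HMOX1 stood at 306 with chaetocin and 970.2 with chetomin at 5 h against 15.9 with vehicle, and MYC at 23.1 and 39 against 209.

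None of the genes named above was called with MeS-chaetocin or MeS-chetomin at 5 h. HMOX1 stood at 48.3 ± 2.67 with MeS-chaetocin, a log2 difference of 1.55 ± 0.22 with a 95% interval of 1.00 to 2.10. It did not pass the correction (adjusted p 1) in the 4-library fit and passed when all libraries of the time point shared the spread (adjusted p 0.0187). WNT16 stood at 10 ± 4.04 with MeS-chaetocin against 26.4 ± 5.32 with vehicle. HSPA1A (0.33, interval -0.33 to 0.99), MYC (-0.06, interval -0.60 to 0.48), MT1X (-0.28), MT1E (-0.28), MT1F (0.04), MT2A (-0.21), SLC30A1 (-0.52, interval -1.32 to 0.28), EP300 (0.01) and CREBBP (-0.14) were not called. With MeS-chetomin, HMOX1 (0.21, interval -0.25 to 0.68), HSPA1A (0.08, interval -0.36 to 0.53), MYC (0.31, interval -0.05 to 0.67), MT1X (-0.02, interval -0.41 to 0.37), MT1E (-0.33), MT1F (-0.32), MT2A (-0.20) and SLC30A1 (-0.18) were not called either. EP300 stood at 1.16 and CREBBP at 0.89 with MeS-chetomin, each with an adjusted p of 0.266. Both were called with the replicate number as a block (adjusted p 0.00235 and 0.0242), as were MTF1 (0.91, adjusted p 0.0274), TXNRD1 (0.80, 0.00177), HIF1A (0.70, 0.0217) and ATF3 (0.75, 0.0245).

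For MeS-chaetocin at 5 h limma called 0 of 14178 genes, with 105 at an unadjusted p under 0.05, and the authors' deposited table calls 7, 5 up and 2 down. In that table HMOX1 (log2 fold change 1.61, q 3.52e-10), OSGIN1 (1.15, q 6.46e-05) and WNT16 (-1.53, q 3.52e-10) are among them. OSGIN1 and WNT16 were chosen for the MeS compounds, here and at 12 h, after their values were seen. Leaving out MeS-chaetocin replicate 1 gave 56 genes, MeS-chaetocin replicate 2 gave 25 and vehicle replicate 2 gave 1. In the simulated data 21 of 100 genes shifted by 1 and 89 of 100 shifted by 2 were recovered in this comparison, and 17 unchanged genes were called.

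With MeS-chetomin at 5 h limma called 20 of 14184 genes, 11 up and 9 down, with 2290 at an unadjusted p under 0.05 and 1149 called with the replicate number as a block. With a shared spread 0 genes were called, which ended all 20 calls. The authors' deposited table calls 23, 9 of them the same as here. Among the 20 was 1 of 2 entries with the symbol SDHD (ENSG00000255292, chromosome 11, 112086903 to 112193805), at 36.5 ± 5.95 against 0.46 ± 0.651 with vehicle (4.75 ± 0.34, adjusted p 0.00608). RBM14-RBM4, a read-through of adjacent RNA-binding protein genes (2.44 ± 0.21, adjusted p 0.00638), and the DNA damage protein MDC1 (1.60 ± 0.18, adjusted p 0.0251) lost their calls on the authors' CPM scale (adjusted p 0.205 and 0.501), where 8 genes were called. Leaving out MeS-chetomin replicate 1 gave 80 genes and replicate 2 gave 59, while leaving out either vehicle replicate gave 0 and ended the calls of all 6 named genes. MDC1 was also lost without MeS-chetomin replicate 1 (0.0835) or 2 (0.121).

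No list member was called with either MeS compound at 5 h, and 1 NRF2 target with MeS-chaetocin was called adjusted over the list alone. Even so, 5 lists passed camera for MeS-chaetocin with shifts of 0.13 for NRF2 targets (adjusted p 3.53e-06), -0.21 for histones (0.0139), 0.09 for heat shock (0.0343), -0.28 for metallothioneins (0.0421) and 0.30 for markers of other cell types (0.0488). Each had adjusted p = 0.961 with an estimated correlation. The count of 5 became 3 without MeS-chaetocin replicate 2 and 1 without vehicle replicate 1. For MeS-chetomin 3 lists passed, the proteasome (shift -0.40, adjusted p 0.000121), histone methyltransferases (0.41, adjusted p 0.0199) and histones (-0.35, adjusted p 0.0256), each with adjusted p = 0.949 with an estimated correlation. Without MeS-chetomin replicate 2, 1 list passed.

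By 12 h chaetocin had lowered every measured metallothionein on the deposited scale. MT1X fell from 148 ± 28.3 to 54.8 ± 3.02 (-1.40 ± 0.17, adjusted p 0.00157), MT1E fell by 0.86 (adjusted p 0.0112), and SLC30A1 fell from 3.69 ± 1.12 to 0.875 ± 0.389 (-1.32 ± 0.25, adjusted p 0.00744). MT2A (ENSG00000125148, chromosome 16, 56608199 to 56609497; -0.90, adjusted p 0.0147) and MT1F (-0.83, adjusted p 0.037) also fell, but were not called on the authors' CPM scale (adjusted p 0.0603 and 0.122) or under median-of-ratios scaling (0.0579 and 0.0964). Without chaetocin replicate 1 or 2 none of these genes kept its call, with adjusted p 0.07 and 0.0781 for MT1X, 0.165 and 0.19 for MT1E, and 0.135 and 0.0837 for SLC30A1. The values were 0.169 and 0.225 for MT2A, and 0.235 and 0.274 for MT1F, which also stood at 0.08 without vehicle replicate 2. The list of 5 thus had 5 down, also 5 adjusted over the list alone, and 3 on the authors' CPM scale, and shifted by -0.74 (camera adjusted p 0.0365; adjusted p = 0.512 with an estimated correlation). The MT1 genes are close paralogs that share reads. MTF1 rose (1.05 ± 0.20, adjusted p 0.00681; 0.122 and 0.134 without chaetocin replicates 1 and 2), while EP300 (-0.23, adjusted p 0.418) and CREBBP (-0.29, adjusted p 0.259) were not called.

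HMOX1 stood at 1089 ± 27.6 with chaetocin at 12 h against 22.3 ± 3.55 with vehicle (5.55 ± 0.15, adjusted p 0.000129), NR4A1 at 394 ± 56.7 against 8.9 ± 0.318 (5.31 ± 0.15) and HSPA1A at 518 ± 49.2 against 16 ± 3.59 (4.95 ± 0.18). CLDN6, a tight junction protein (ENSG00000184697, chromosome 16, 3014712 to 3020071), rose from 0.08 ± 0.113 to 47.5 ± 9.61 (5.48 ± 0.24), and the alpha globin gene HBA2, whose reads can fall on its near-identical copy HBA1, rose by 5.25 ± 0.24. MYC fell by 1.77 ± 0.16 (adjusted p 0.000699). The linker histone gene H1F0 (ENSG00000189060, chromosome 22, 37805093 to 37807436) fell from 499.9 ± 20.2 to 57.8 ± 1.95 (-3.09 ± 0.12, adjusted p 0.000197), and the histone methyltransferase gene KMT2A fell by 1.77 (adjusted p 0.0726 and 0.0685 without chaetocin replicates 1 and 2).

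Heat shock genes rose in 23 of 26 cases with chaetocin at 12 h, also 23 adjusted over the list alone (shift 1.35, camera adjusted p 1.42e-11; adjusted p = 0.444 with an estimated correlation). Endoplasmic reticulum chaperones rose in 13 of 18 (14 adjusted over the list alone), including the lumenal chaperone HSPA5 at 1.52 (shift 1.17, adjusted p 1.81e-06; adjusted p = 0.444 with an estimated correlation). NRF2 targets rose in 14 of 28 (15 adjusted over the list alone), among them SRXN1, which reduces oxidised peroxiredoxins (1.93 ± 0.12), and MAFG (2.90 ± 0.15), with a shift of 0.74 (adjusted p 5.55e-06; adjusted p = 0.444 with an estimated correlation). The integrated stress response list had 11 up and 1 down of 23, or 11 and 2 adjusted over the list alone, with ATF3 at 3.96 ± 0.14 and DDIT3 at 3.47 ± 0.14 (shift 0.88, adjusted p 0.000811; adjusted p = 0.444 with an estimated correlation). Immediate early genes had 18 up and 10 down of 29, the same adjusted over the list alone (shift 1.53, adjusted p 0.00104; adjusted p = 0.598 with an estimated correlation). Of 27 proteasome genes 11 rose and 2 fell, the same adjusted over the list alone, and 19 rose and 0 fell on the authors' CPM scale (shift 0.38, adjusted p 0.0335; adjusted p = 0.444 with an estimated correlation). Mitochondrially encoded transcripts moved with these lists, 9 of 13 up, also 9 adjusted over the list alone (shift 0.94, adjusted p 0.00073; adjusted p = 0.619 with an estimated correlation). So did 5 of 6 markers of other cell types, with the endothelial gene PECAM1 at 2.04, CD68 at 1.80 (adjusted p 0.0501 without chaetocin replicate 1) and ALB, listed at 0 in vehicle, at a level of 3.75 ± 0.785 (shift 1.39, adjusted p 0.00767; adjusted p = 0.444 with an estimated correlation).

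In all, limma called 7230 of 15377 genes with chaetocin at 12 h, 3102 up and 4128 down, with 1570 and 1784 past 1 on the log2 scale. On the authors' CPM scale 4359 rose and 2467 fell, so increases made up 42.9% of calls on the deposited scale and 63.9% on the authors'. The authors' deposited table calls 9267 genes, 6412 of them shared in direction with the calls here. Without chaetocin replicate 1 the count was 1628 and without replicate 2 it was 1632, and each ended the calls of 78 of the 126 named genes, with HMOX1 and MYC kept.

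Chetomin at 12 h lowered MT1X to 43.3 ± 3.61 (-1.74 ± 0.19, adjusted p 0.000514), MT2A (-1.10, adjusted p 0.00601), MT1E (-0.93, adjusted p 0.00963) and SLC30A1 to 1.02 ± 0.099 (-1.20 ± 0.24, adjusted p 0.00681). Without chetomin replicate 1 or 2 these calls ended, with adjusted p 0.0812 and 0.0709 for MT1X, 0.168 and 0.19 for MT2A, 0.196 and 0.191 for MT1E, and 0.133 and 0.173 for SLC30A1. The call of MT1E also ended under median-of-ratios scaling (0.0523). MT1F (-0.58, adjusted p 0.127), EP300 (-0.67, adjusted p 0.0982), CREBBP (-0.59, adjusted p 0.0951) and MTF1 (0.37, adjusted p 0.281) were not called on the deposited scale. MTF1 was called on the authors' CPM scale (0.84, adjusted p 0.0199). With a shared spread MT1F (adjusted p 0.0396), EP300 (0.0365) and CREBBP (0.0309) were called, and EP300 was also called with a block (0.0409). The metallothionein list had 4 of 5 down on both scales and adjusted over the list alone, and shifted by -0.95 (camera adjusted p 0.0121; adjusted p = 0.599 with an estimated correlation).

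LINC00659 reached 519 ± 7.69 with chetomin at 12 h (7.67 ± 0.18, adjusted p 8.35e-07) and HMOX1 1486 ± 20.6 (6.00 ± 0.17, adjusted p 1.72e-06). IGF2-AS, antisense to the growth factor gene IGF2 (ENSG00000099869, chromosome 11, 2140501 to 2148666), rose from 0.02 ± 0.0283 to 60.2 ± 1.52 (5.91 ± 0.24); as for LINC00659, the strand used in counting is not given, so its reads are uncertain here and below. ARC, an activity-dependent gene of neurons (ENSG00000198576, chromosome 8, 142611044 to 142614472, 3 exons), rose to 171 ± 10.7 from 5.79 ± 1.41 (4.68 ± 0.20). WNT16 (ENSG00000002745, chromosome 7, 121325367 to 121341104, 5 exons) fell from 33.4 ± 2.25 to 2.5 ± 1.07 (-3.33 ± 0.27, adjusted p 0.000174), H1F0 fell by 2.49 ± 0.16 and MYC fell by 1.84 ± 0.17.

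Among the lists, heat shock had 19 of 26 up with chetomin at 12 h (21 adjusted over the list alone; shift 1.17, camera adjusted p 5.06e-11; adjusted p = 0.27 with an estimated correlation). The integrated stress response had 16 of 23 up (17 adjusted over the list alone), including TRIB3 (ENSG00000101255, chromosome 20, 362835 to 397559) at 3.21 ± 0.16 and the hormone gene FGF21 at 2.17 (shift 1.21, adjusted p 3.81e-09; adjusted p = 0.383 with an estimated correlation). NRF2 targets had 19 of 28 up, or 21 up and 1 down adjusted over the list alone, with OSGIN1 at 2.80 ± 0.23, GCLM at 2.66 ± 0.22 and the thioredoxin reductase gene TXNRD1 at 1.19 (shift 0.96, adjusted p 5.94e-09; adjusted p = 0.27 with an estimated correlation). Endoplasmic reticulum chaperones had 8 of 18 up, also 8 adjusted over the list alone (shift 0.67, adjusted p 0.000108; adjusted p = 0.396 with an estimated correlation). Immediate early genes had 16 up and 7 down, or 18 and 8 adjusted over the list alone (shift 0.92, adjusted p 0.00122; adjusted p = 0.636 with an estimated correlation). Of 13 Wnt targets 7 fell, or 6 on the authors' CPM scale and 7 adjusted over the list alone, among them DKK1 (-1.26), CD44 (-1.26) and the receptor regulator RNF43 (-1.19), with a shift of -0.50 (adjusted p 0.0255; adjusted p = 0.636 with an estimated correlation). Proteasome genes had 5 of 27 up, also 5 adjusted over the list alone, and 19 on the authors' CPM scale (shift 0.47, adjusted p 0.00678; adjusted p = 0.599 with an estimated correlation). Beside these, 4 of 13 mitochondrially encoded transcripts rose, also 4 adjusted over the list alone (shift 0.68, adjusted p 0.0042; adjusted p = 0.636 with an estimated correlation), and 4 of 6 markers of other cell types (shift 0.90, adjusted p 0.0112; adjusted p = 0.581 with an estimated correlation).

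Without chetomin replicate 1 or 2 OSGIN1 (adjusted p 0.0646 and 0.0624), GCLM (0.0607 and 0.0628), TXNRD1 (0.161 and 0.153), DKK1 (0.0849 and 0.095), CD44 (0.0544 and 0.0989) and RNF43 (0.0998 and 0.119) lost their calls. For chetomin at 12 h limma called 5503 of 15381 genes, 2397 up and 3106 down, and on the authors' CPM scale 3444 up and 1575 down, so the share of increases was 43.6% or 68.6%. The authors' deposited table calls 8211, 4986 of them shared in direction with the calls here. Leaving out chetomin replicate 1 gave 880 genes and replicate 2 gave 989, and of the 121 named genes 85 and 87 lost their calls, with HMOX1 and MYC kept.

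Lists that did not pass camera at 12 h still held called genes. Among all genes tested 3102 rose and 4128 fell of 15377 with chaetocin, and 2397 and 3106 of 15381 with chetomin. Such counts alone show no response of a list. List counts are up and down on the deposited scale, then on the authors' CPM scale, with the camera adjusted p, and chaetocin comes first. Zinc transporters (18 genes) had 1 and 4, then 2 and 3, with chaetocin (0.37), and 1 and 4, then 0 and 2, with chetomin (0.224). Interferon response genes (15) had 1 and 8, then 3 and 6, with chaetocin (0.225), and 1 and 6, then 3 and 3, with chetomin (0.216). Among them the antiviral gene IFIT1 stood at -1.42 ± 0.14 and at -1.22 ± 0.16 (adjusted p 0.0595 and 0.0536 without chetomin replicates 1 and 2). S phase genes (23) had 8 and 1, then 14 and 0, with chaetocin (0.0613), and 2 and 2, then 9 and 1, with chetomin (0.371). Mitosis genes (23) had 3 and 4, then 5 and 0 (0.762), and 2 and 0, then 10 and 0 (0.114). Ribosome biogenesis genes (24) had 1 and 9, then 3 and 5 (0.058), and 0 and 5, then 4 and 4 (0.211). Integrator genes (15) had 0 and 6, then 1 and 2 (0.218), and 1 and 3, then 0 and 1 (0.224). Acetyltransferases and deacetylases (22) had 2 and 5, then 4 and 3 (0.465), and 0 and 3, then 1 and 3 (0.12). Histone methyltransferases (20) had 2 and 6, then 5 and 4 (0.595), and 0 and 6, then 1 and 3 (0.114). NF-kB targets (14) had 4 and 4, then 4 and 1 (0.792), and 2 and 6, then 3 and 2 (0.599). Apoptosis regulators (17) had 2 and 5, then 3 and 3 (0.792), and 3 and 3, then 6 and 1 (0.855). Iron and copper genes (18) had 4 and 6, then 6 and 6 (0.792), and 5 and 6, then 5 and 3 (0.928). Intestinal genes (8) had 2 and 2, then 4 and 1 (0.792), and 0 and 2, then 3 and 1 (0.928). Histones (16) had 1 and 5, then 3 and 2 (0.551), and 2 and 1, then 4 and 1 (0.302). p53 targets (28) had 2 and 11, then 4 and 5 (0.172), and 4 and 7, then 4 and 2 (0.221). Wnt targets (13) with chaetocin had 0 and 7, then 2 and 5 (0.099).

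**Figure D2:**
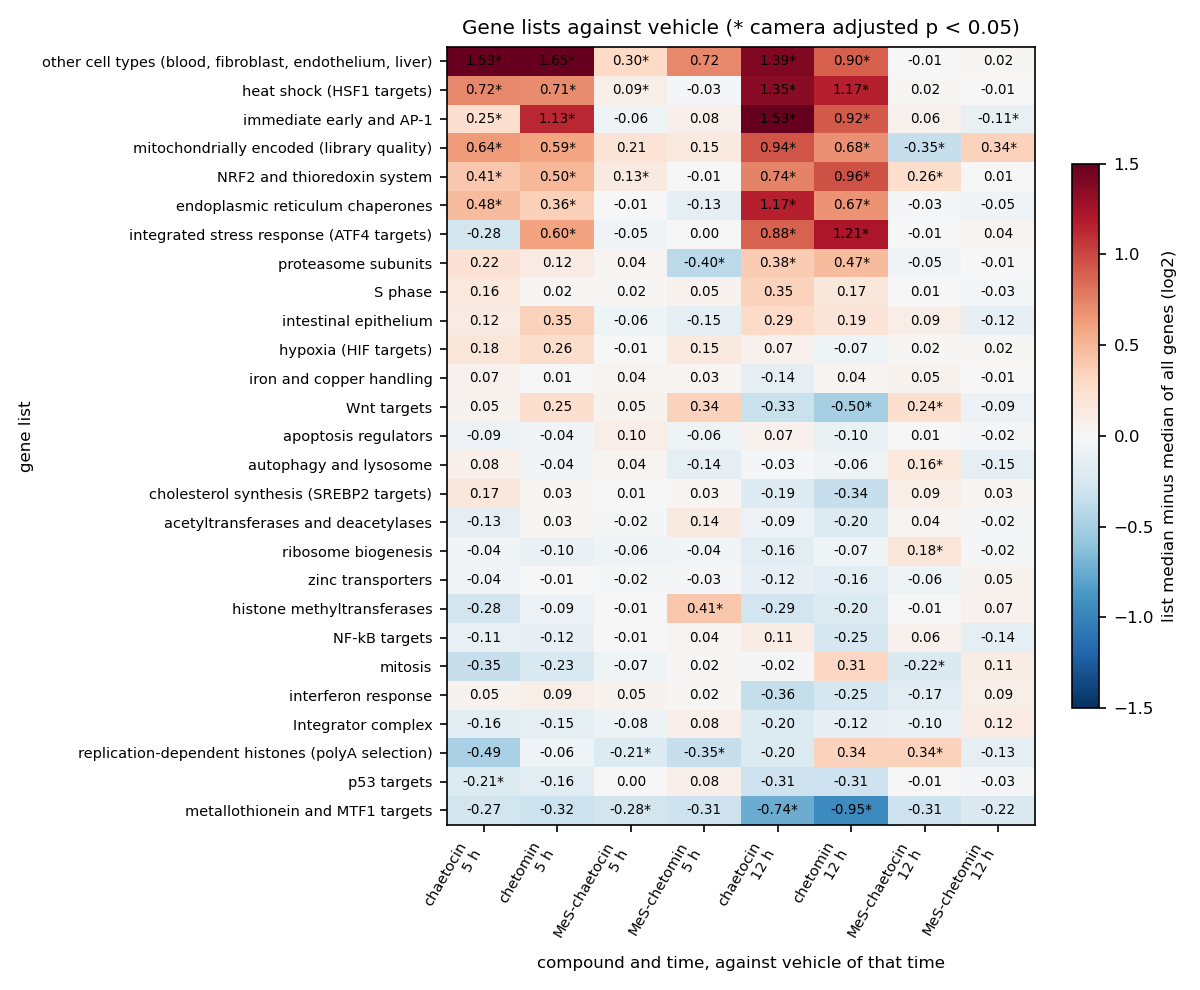
Heat map of the median log2 difference of each gene list minus the median of all genes, for the 8 comparisons with vehicle; stars mark a camera adjusted p under 0.05 at a preset correlation of 0.01. The heat shock list stood at 0.72 and 0.71 with chaetocin and chetomin at 5 h and at 1.35 and 1.17 at 12 h, against 0.09 with MeS-chaetocin at 5 h.

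The MeS compounds at 12 h left HMOX1 at 38.7 ± 0.679 (MeS-chaetocin) and 19.9 ± 0.721 (MeS-chetomin), log2 differences of 0.77 ± 0.17 (95% interval 0.36 to 1.19, adjusted p 0.786) and -0.15 (interval -0.58 to 0.28). WNT16 stood at 17.1 ± 2.5 and 38 ± 0.842 against 33.4 ± 2.25 with vehicle. MT1X was at -0.29 with MeS-chaetocin and -0.31 (interval -0.71 to 0.09) with MeS-chetomin, MYC at 0.26 and -0.14 (interval -0.42 to 0.14), and HSPA1A at 0.31 and -0.47 (interval -1 to 0.06), none called. Also not called were MT1E (-0.31 and -0.21), MT1F (-0.32 and -0.15), MT2A (-0.07 and -0.36), SLC30A1 (-0.17 and 0.42), EP300 (-0.08 and 0.43, the latter with an adjusted p of 0.821) and CREBBP (0.06 and 0.08).

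limma called 0 of 15216 genes with MeS-chaetocin at 12 h, with 756 at an unadjusted p under 0.05 and 37 in the authors' deposited table, where WNT16 (-1.12, q 4.02e-06), HMOX1 (0.82, q 0.000415) and OSGIN1 (0.82, q 0.0298) appear again. It called 0 of 15197 with MeS-chetomin, with 416 at an unadjusted p under 0.05 and 10 in the authors' deposited table. With the replicate number as a block the counts were 5 and 6. Simulated shifts of 1 were recovered for 62 and 72 of 100 genes in these comparisons. No list member was called with either compound, but 7 lists passed camera for MeS-chaetocin: NRF2 targets (shift 0.26, adjusted p 0.000859), Wnt targets (0.24, 0.00593) and histones (0.34, 0.00769), each with adjusted p = 0.631 with an estimated correlation. The others were mitochondrially encoded genes (-0.35, 0.0238) and mitosis (-0.22, 0.0429), each with adjusted p = 0.963 with an estimated correlation, autophagy (0.16, 0.0429; adjusted p = 0.875 with an estimated correlation) and ribosome biogenesis (0.18, 0.0429; adjusted p = 0.718 with an estimated correlation). Without MeS-chaetocin replicate 1, 2 lists passed, and without either vehicle replicate 4 did. For MeS-chetomin the mitochondrially encoded (0.34, 0.000114) and immediate early lists (-0.11, 0.0122) passed, each with adjusted p = 0.73 with an estimated correlation, and without vehicle replicate 1 the count of 2 became 4.

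**Figure D3:**
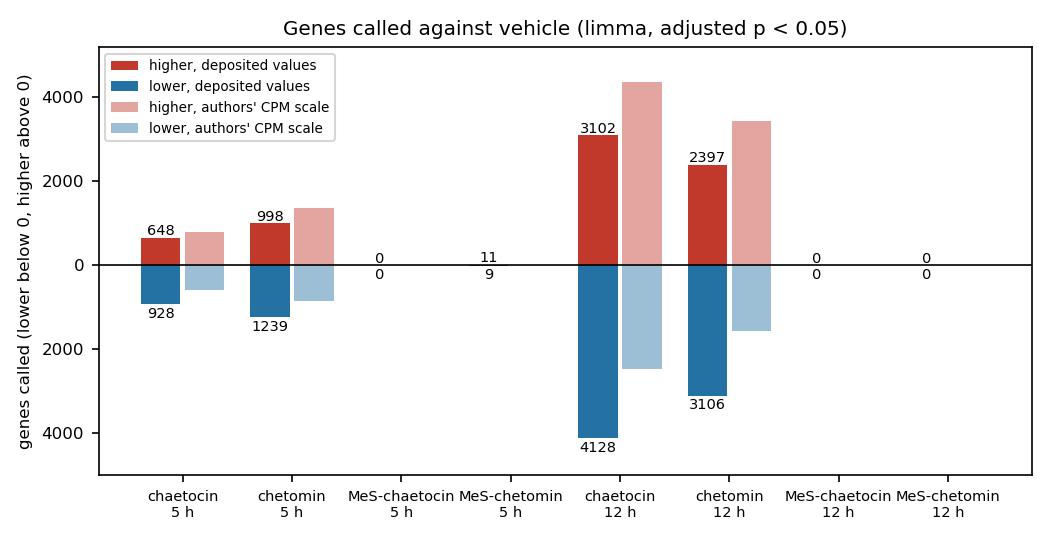
Bars give the number of genes limma called up and down against vehicle for each compound and time, on the deposited values and on the authors' CPM scale. Chaetocin and chetomin gave 1576 and 2237 genes at 5 h and 7230 and 5503 at 12 h on the deposited values, MeS-chetomin gave 20 at 5 h (1149 with the replicate number as a block and 0 with a shared spread), and the other MeS comparisons gave 0.

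Chaetocin and chetomin called many of the same genes in the same direction. At 5 h both raised 501 and lowered 660 of 14216 genes, where independent lists would share 45.4 and 80.9, and 3 genes were called in opposite directions. At 12 h both raised 2072 and lowered 2618 of 15377, against 483.3 and 833.8 for independent lists, with 8 called in opposite directions. The comparisons share their vehicle libraries, so part of the excess may come from the shared controls. In 100 simulations with shared vehicle libraries and no effect, the highest shared count was 1 at each time. With no effect few calls can arise. The simulations therefore cannot measure what the shared vehicle adds among genes that do respond. The correlation of log2 differences, which is across genes and so not across independent replicates, was 0.82 at 5 h and 0.89 at 12 h against 0.5 in the simulations, and the covariance was 0.301 and 0.602 against 0.035 and 0.02. Without chaetocin replicate 1 or 2 the shared counts were 434 and 492 at 5 h and 1353 and 1360 at 12 h, and without chetomin replicate 1 or 2 they were 416 and 457, and 836 and 936.

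**Figure D4:**
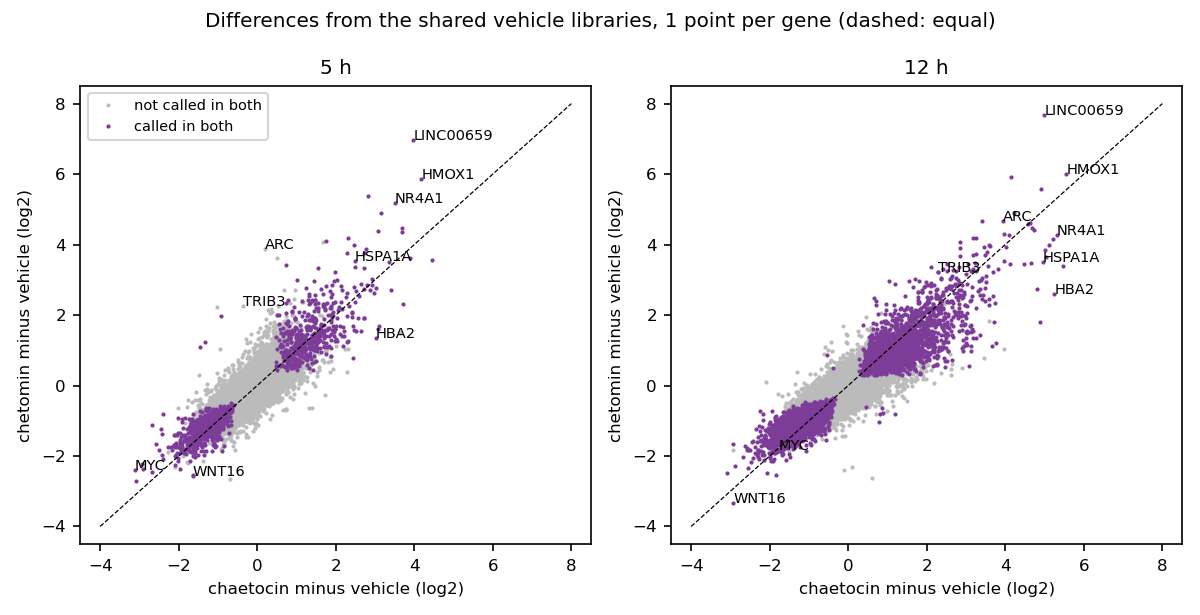
Log2 difference from vehicle with chetomin against that with chaetocin for each gene at 5 h and 12 h, with genes called in both comparisons in purple. The correlation across genes was 0.82 at 5 h and 0.89 at 12 h, and 0.5 in simulations with shared vehicle libraries and no effect.

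Compared directly at 5 h, the difference of chaetocin minus chetomin was -3.67 for ARC (95% interval -4.09 to -3.25, adjusted p 0.000281), with 4.98 ± 0 against 75.4 ± 0.863, and -2.64 for TRIB3 (-2.93 to -2.35, adjusted p 0.000279), with 34.8 ± 0.0495 against 222 ± 12.8 and 45.3 ± 0.255 with vehicle. DDIT4, a stress-induced inhibitor of mTORC1 signalling, differed by -2.91 (-3.20 to -2.61), ATF3 by -2.33 (-2.91 to -1.75; adjusted p 0.0105, and 0.0526 to 0.102 when any 1 chaetocin or chetomin replicate was left out), HMOX1 by -1.66 (-1.97 to -1.36, adjusted p 0.00495) and HSPA1A by -1.05 (-1.33 to -0.76, adjusted p 0.0125). RSRP1, a splicing-related gene (1.48, 1.10 to 1.86, adjusted p 0.0106), and the cyclin gene CCNL1 (1.29) were higher with chaetocin. DNAJB1 (-1.11, adjusted p 0.0544) and DDIT3 (-1.11, adjusted p 0.0509) were not called, though DNAJB1 was on the authors' CPM scale (0.0403) and DDIT3 with a shared spread (0.0349). Also not called were TXNRD1 (-0.34, adjusted p 0.76), MYC (-0.73, -1.03 to -0.43, adjusted p 0.0595; 0.0466 with a shared spread), MT1X (0.17, -0.18 to 0.52, adjusted p 0.727) and SLC30A1 (0.07, -0.46 to 0.61).

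At 5 h limma called 109 of 14216 genes between chaetocin and chetomin, 18 higher and 91 lower with chaetocin, and 65 (6 and 59) on the authors' CPM scale. Without chaetocin replicates 1 and 2 in turn the count was 11 and 17, without chetomin replicates 15 and 10, and without vehicle replicates 185 and 186. Of the 15 named genes called, 10 and 9 lost their calls without chaetocin replicates 1 and 2, and 11 without each chetomin replicate, HMOX1 among the last (adjusted p 0.055 and 0.0545). RSRP1 (0.0715 to 0.132), CCNL1 (0.0863 to 0.159) and HSPA1A (0.08 to 0.17) lost their calls when any 1 chaetocin or chetomin replicate was left out, and HSPA1A also with the replicate number as a block (adjusted p 0.0638).

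In the direct comparison at 12 h HSPA1A was higher with chaetocin by 1.45 (1.08 to 1.82, adjusted p 0.00302), and VEGFA, an angiogenic factor, by 0.80 (0.50 to 1.11, adjusted p 0.0148). The heat shock genes HSPA1B (0.40, adjusted p 0.235) and DNAJB1 (-0.25, adjusted p 0.296) were not called. OVOL1, an epithelial transcription factor, stood at 108 ± 9.99 with chaetocin and 17.6 ± 1.51 with chetomin (2.55, 2.20 to 2.89, adjusted p 0.000488), and HBA1 differed by 3.08 (2.24 to 3.92). LINC00659 was lower with chaetocin by 2.67 on the log2 scale (-2.67, -3.01 to -2.32), as was IGF2-AS (-1.75). HMOX1 (-0.45, -0.76 to -0.14, adjusted p 0.0983; 0.0322 with a shared spread), DDIT3 (-0.24, -0.52 to 0.04), MYC (0.07, -0.31 to 0.45) and MT1X (0.33, -0.03 to 0.70, adjusted p 0.275) were not called. limma called 723 of 15377 genes, 526 higher and 197 lower with chaetocin, and 614 and 120 on the authors' CPM scale, so that 72.8% or 83.7% were higher. Without chaetocin replicates the count was 188 and 222, without chetomin replicates 65 and 0, and without vehicle replicates 1514 and 1468. Of the 12 named genes called, 8 and 12 lost their calls without chetomin replicates 1 and 2, and 3 and 2 without chaetocin replicates, VEGFA in each case (adjusted p 0.112 to 0.149).

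Each parent compound was also compared with its sulfide-depleted analog at the same dose and time. At 5 h chaetocin minus MeS-chaetocin was 2.64 for HMOX1 (95% interval 2.24 to 3.03, adjusted p 0.00335), 4.43 for EGR1 (3.88 to 4.98), 2.16 for HSPA1A (1.68 to 2.64, adjusted p 0.0058) and -3.06 for MYC (-3.47 to -2.66, adjusted p 0.00321). MT1X (-0.18, -0.73 to 0.37, adjusted p 0.741) and SLC30A1 (-0.80, -1.43 to -0.18, adjusted p 0.133) were not called at 5 h. At 12 h the differences were 4.78 for HMOX1 (4.47 to 5.08, adjusted p 1.66e-05), 4.64 for HSPA1A (4.22 to 5.06), -2.03 for MYC, -1.11 for MT1X (-1.5 to -0.72, adjusted p 0.00141) and -1.15 for SLC30A1 (adjusted p 0.00527). MT2A (-0.82, adjusted p 0.0111) was also called, but not under median-of-ratios scaling (adjusted p 0.0743), MT1E (-0.55, adjusted p 0.0345) not on the authors' CPM scale (-0.30, adjusted p 0.193) or with a block (0.06), and MT1F was not called (-0.50, adjusted p 0.111).

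limma called 897 of 14174 genes between chaetocin and MeS-chaetocin at 5 h, 414 higher and 483 lower, and 531 and 312 on the authors' CPM scale (46.2% and 63% higher; median of all genes -0.10 and 0.07). At 12 h it called 8130 of 15213, 3259 higher and 4871 lower, and 4731 and 2982 on the authors' CPM scale (40.1% and 61.3%; medians -0.17 and 0.12). At 5 h the count was 148 and 185 without chaetocin replicates 1 and 2, and 278 and 274 without vehicle replicates 1 and 2. HSPA1A lost its call without chaetocin replicate 1 (adjusted p 0.0513). At 12 h MT2A lost its call without MeS-chaetocin replicate 1 (0.0639) or chaetocin replicate 2 (0.0938), and MT1E without MeS-chaetocin replicate 1 (0.175) or chaetocin replicates 1 and 2 (0.114 and 0.177).

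Chetomin minus MeS-chetomin at 5 h was 5.63 for HMOX1 (95% interval 5.33 to 5.94, adjusted p 9.42e-07), 3.45 for HSPA1A (3.16 to 3.75), -2.70 for MYC (-2.98 to -2.42) and -1.22 for SLC30A1 (adjusted p 0.00749). MT1X (-0.61, -0.95 to -0.27, adjusted p 0.0157) lost its call on the authors' CPM scale (-0.28, adjusted p 0.31), with a shared spread (0.0519), and when any 1 chetomin or MeS-chetomin replicate was left out (0.0632 to 0.115). EP300 (ENSG00000100393, chromosome 22, 41091786 to 41180079, 33 exons) differed by -1.16 (adjusted p 0.0195) and CREBBP (ENSG00000005339, chromosome 16, 3725054 to 3880726, 37 exons) by -0.99 (adjusted p 0.0176). Against vehicle they stood at 0 and -0.09 with chetomin but at 1.16 and 0.89 with MeS-chetomin, so the gap lay mostly with MeS-chetomin. Both calls ended with a shared spread (adjusted p 0.135 and 0.122). MTF1 stood at -0.22, not called, and was higher with chetomin on the authors' CPM scale (0.69, adjusted p 0.0416). By 12 h HMOX1 differed by 6.15 (5.84 to 6.47, adjusted p 1.21e-06), HSPA1A by 3.97 (3.57 to 4.37), WNT16 by -3.51, H1F0 by -2.59, MT1X by -1.43 (-1.78 to -1.08, adjusted p 0.000453) and SLC30A1 by -1.62. EP300 (-1.10, adjusted p 0.00914) lost its call on the authors' CPM scale (-0.51, adjusted p 0.107).

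limma called 4637 of 14181 genes between chetomin and MeS-chetomin at 5 h, 1243 higher and 3394 lower, and 2770 and 1833 on the authors' CPM scale (26.8% and 60.2% higher; median of all genes -0.19 and 0.08). At 12 h it called 7146 of 15197, 2714 higher and 4432 lower, and 4394 and 2312 on the authors' CPM scale (38% and 65.5%; medians -0.18 and 0.11). At 5 h the count was 2132 and 1624 without MeS-chetomin replicates 1 and 2, and 2162 and 2087 without chetomin replicates 1 and 2. At 12 h it was 3661 and 3690 without MeS-chetomin replicates 1 and 2, and 3366 without chetomin replicate 2. At 5 h SLC30A1 lost its call without MeS-chetomin replicate 1 (adjusted p 0.0632) or chetomin replicate 1 (0.0587), EP300 without MeS-chetomin replicate 2 (0.144) or chetomin replicate 2 (0.135), and CREBBP whichever of the 4 was left out (0.0505 to 0.145). At 12 h EP300 lost it without MeS-chetomin replicate 1 (0.0586) or chetomin replicate 2 (0.079).

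Between MeS-chaetocin and MeS-chetomin, HMOX1 differed by 1.33 at 5 h (95% interval 0.89 to 1.78, adjusted p 0.634) and by 0.93 at 12 h (0.58 to 1.27, adjusted p 0.133), higher with MeS-chaetocin and not called. HSPA1A at 12 h stood at 0.78 (0.31 to 1.26, adjusted p 0.133), MYC at 0.39 (0.12 to 0.67, adjusted p 0.133) and MT1X at 0.01 (-0.38 to 0.41), none called. With a shared spread HMOX1 (adjusted p 0.0461), HSPA1A (0.0485) and HSPA1B (0.76, adjusted p 0.0485) were called at 12 h. limma called 0 of 14167 genes at 5 h, with 558 at an unadjusted p under 0.05, and 1 of 15162 at 12 h, with 4145. The 1 gene, the pseudogene ZBTB45P1 (ENSG00000225108, 2.22 ± 0.13, adjusted p 0.0217), was chosen after its values were seen. At 5 h the count was 4 and 504 without MeS-chaetocin replicates 1 and 2. At 12 h it was 0 without MeS-chaetocin replicate 2 or either MeS-chetomin replicate, and 2164 and 2142 without vehicle replicates 1 and 2. With a shared spread it was 583.

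The effect of each compound was compared between 12 h and 5 h, each against the vehicle of its own time. The difference at 12 h minus that at 5 h with chaetocin was 1.37 for HMOX1 (95% interval 0.87 to 1.88, adjusted p 0.0103), 2.46 for HSPA1A (1.91 to 3.01, adjusted p 0.000947), 2.17 for SRXN1 (1.74 to 2.61, adjusted p 0.000622) and 2.01 for DDIT3 (1.43 to 2.59, adjusted p 0.0033). The fall of MYC was smaller at 12 h, by 1.36 (0.85 to 1.86, adjusted p 0.011). MT1X stood at -0.94 (-1.5 to -0.38, adjusted p 0.0683), not called, and was called with a shared spread (0.033). For chetomin HMOX1 (0.16, -0.32 to 0.63, adjusted p 0.71), HSPA1A (-0.04, -0.57 to 0.49) and MT1X (-1.10, -1.67 to -0.54, adjusted p 0.0746) were not called, but MT1X was with a shared spread (0.0269) or a block (0.0222), and SRXN1 stood at 1.3 (adjusted p 0.0235). limma called 615 of 14066 genes for chaetocin, 488 up and 127 down, and 609 on the authors' CPM scale; for chetomin it called 70 of 14069, 46 up and 24 down, and 44 on the authors' CPM scale. With a block the counts were 397 and 719, and with a shared spread 1366 and 699. It called 0 of 14022 for MeS-chaetocin, with 151 at an unadjusted p under 0.05, and 0 of 14029 for MeS-chetomin, with 1479.

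Counts of the time comparisons moved with single libraries. For chaetocin the count was 306 and 336 without chaetocin 5 h replicates 1 and 2, 382 without vehicle 5 h replicate 1, 250 and 269 without chaetocin 12 h replicates 1 and 2, and 318 and 290 without vehicle 12 h replicates 1 and 2. HMOX1 and MYC lost their chaetocin time calls without chaetocin 12 h replicate 1 (adjusted p 0.06 and 0.0659). For chetomin it was 14 and 8 without chetomin 5 h replicates 1 and 2, 5 and 581 without vehicle 5 h replicates, 9 without either chetomin 12 h replicate, and 181 and 1 without vehicle 12 h replicates 1 and 2. SRXN1 kept its call only without vehicle 5 h replicate 2 or vehicle 12 h replicate 1. For MeS-chaetocin it was 1 without MeS-chaetocin replicate 1 of 5 h or of 12 h. For MeS-chetomin it was 1 without MeS-chetomin 5 h replicate 1, 2 without MeS-chetomin 12 h replicate 1 and 1 without vehicle 12 h replicate 2.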

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

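The test behind these results, an interaction of compound with time in limma (adjusted p under 0.05, 8 libraries), was fixed before the values were seen; the values on the authors' CPM scale were a check chosen after them. Each result below is a gene whose log2 difference from vehicle was not the same at 12 h as at 5 h, given as the difference at 12 h minus that at 5 h. Both times have their own vehicle libraries.

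With chaetocin 615 genes differed between the times. The difference from vehicle was higher at 12 h for IGF2-AS by 4.09, AC005336.2 by 3.79, ARC by 3.75, PPP1R27 by 3.43 and the antiviral gene TRIM22 by 3.41; IGF2-AS was listed at 0 in vehicle at 5 h, so its value is a difference on the log2(value + 1) scale and not a fold. The strand used in counting is not given, so the reads of IGF2-AS are uncertain. HSPA1A stood at 2.46, ATF3 at 2.21, SRXN1 at 2.17, DDIT3 at 2.01, HMOX1 at 1.37 and VEGFA at 1.09, and MYC, lower than vehicle at both times, stood at 1.36. VEGFA did not pass with the replicate number as a block (adjusted p 0.154). Not every stress gene passed, with DNAJB1 at -0.17 (adjusted p 0.74), TXNRD1 at 0.04 (0.974) and HSPA1B at 1.09 (0.0563; 0.0206 on the authors' CPM scale). Genes lower at 12 h than at 5 h relative to vehicle were EPN3 (-2.71), the epithelial transcription factor EHF (-2.37), the glucose transporter gene SLC2A1 (-2.24), MAGI1 (-2.08) and L3MBTL3 (-2.04). EHF, MAGI1 and L3MBTL3 did not pass on the authors' CPM scale (adjusted p 0.0759, 0.0532 and 0.125). SLC2A1 stood at 155 ± 44.9 with chaetocin at 5 h and 48.4 ± 5.67 at 12 h (SD, n = 2), against 183 ± 49.4 and 275 ± 18.6 with vehicle.

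With chetomin 70 genes differed between the times. The difference from vehicle was higher at 12 h for IGF2-AS (4.27), AC125494.1 (2.83), the mucin gene MUC5AC (2.75), AL160408.2 (2.54), MIR22HG (2.49) and SRXN1 (1.3). MUC5AC was listed at 0 in both vehicle libraries at each time, so no fold is given, and its level was 1.28 ± 0.24 at 5 h and 14.5 ± 3.64 at 12 h. Lower at 12 h than at 5 h relative to vehicle were 1 of 2 entries with the symbol SDHD (-4.46), MAGI1 (-2.13), EHF (-2.13), OSBPL5 (-2.05) and the immediate early gene EGR4 (-1.91). SDHD, MAGI1, EHF and OSBPL5 did not pass on the authors' CPM scale (adjusted p 0.0868, 0.075, 0.0612 and 0.075). The SDHD entry varied within groups, with 42.2 ± 31.8 in vehicle at 12 h, and no explanation was tested for these genes. EGR4 stood at 6.74 ± 0.417 with chetomin at 5 h and 1.07 ± 0.0707 at 12 h.

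The counts moved when single libraries were left out, and many of the calls ended. Leaving out 1 library leaves 1 in its arm, so dependence on a library cannot be told apart from lost precision. Of the 17 named genes called for chaetocin, 6 lost the call without chaetocin 12 h replicate 1 and 1 to 3 without each other library, VEGFA without all but vehicle 5 h replicate 1. Of the 11 for chetomin 8 to 10 lost it when any 1 library was left out, other than vehicle 5 h replicate 2 (0) and vehicle 12 h replicate 1 (1). Without 1 library the chaetocin count ran from 250 (chaetocin 12 h replicate 1) to 652 (vehicle 5 h replicate 2), and the chetomin count from 1 (vehicle 12 h replicate 2) to 581 (vehicle 5 h replicate 2).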

How the results depend on the processing

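Chosen after the values were seen were median-of-ratios scaling, the authors' CPM scale, pseudocounts of 0.1 and 5, the correction for GC content and length, the fit with no trend and the crossed pairing. Across all alternatives 277 counts stayed within 1.5 times the reported one and 145 did not; of values for named genes 11525 kept direction and side of the threshold, 1016 lost the call, 143 gained one and 1 changed direction. That 1 is MTF1 for chetomin against MeS-chetomin at 5 h, at 0.69 (adjusted p 0.0416) on the authors' CPM scale. Where no cause is given below, the cause was not tested. A DESeq2 Wald test and relative log expression factors were not run, since both need counts. Groups of 2 libraries are too few for other splits of the samples. Read counts are not in hand, so what depth limits was judged only by the simulated recovery, lowest at a shift of 1 for the chaetocin time comparison (18 of 100) among the 10 comparisons simulated.

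With a mean CPM of at least 5, which tests fewer genes, the counts were 8 for MeS-chetomin 5 h, 59 for chaetocin against chetomin 5 h, 500 for chaetocin against MeS-chaetocin 5 h, 0 between the MeS compounds at 12 h, and 351, 111 and 1 for the time comparisons of chaetocin, chetomin and MeS-chetomin. When all libraries of a time point shared the spread they were 1 and 0 for MeS-chaetocin and MeS-chetomin at 5 h, 1 for MeS-chaetocin 12 h, 2101 for chaetocin against MeS-chaetocin 5 h, 1550 for chaetocin against chetomin 12 h, 583 between the MeS compounds at 12 h, and 1366, 699 and 1 for the 3 time comparisons.

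Taking the replicate number as a block gave 1149 for MeS-chetomin 5 h, 5 for MeS-chaetocin 12 h, 6 for MeS-chetomin 12 h, 44 for chaetocin against chetomin 5 h, 545 for chaetocin against MeS-chaetocin 5 h, 3 between the MeS compounds at 12 h, and 397 and 719 for the chaetocin and chetomin time comparisons. Blocked counts for chaetocin and chetomin against vehicle were 1511 and 3112 at 5 h and 7056 and 6228 at 12 h. The replicate numbers are not shown to pair libraries: the deviations of compound and vehicle libraries of the same number correlated across genes from -0.57 to 0.74, with only 2 pairs each. Crossing the pairs, done only where that correlation was below -0.1, gave 4666 for chaetocin 5 h, 9050 for chaetocin 12 h, 19 for MeS-chaetocin 12 h and 0 for MeS-chetomin 12 h. The comparisons to cross were picked from the same values, so these counts are not a neutral alternative.

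On the authors' CPM scale the counts were 8 for MeS-chetomin 5 h, 65 for chaetocin against chetomin 5 h and 44 for the chetomin time comparison, and median-of-ratios scaling gave 9 for MeS-chetomin 5 h. A pseudocount of 0.1 gave 60 for chaetocin against chetomin 5 h, 2 between the MeS compounds at 12 h, and 256, 21 and 1 for the time comparisons of chaetocin, chetomin and MeS-chetomin; a pseudocount of 5 gave 6 for MeS-chetomin 5 h and 132 for the chetomin time comparison. The correction for GC content and length gave 11 for MeS-chetomin 5 h, 174 and 1480 for chaetocin against chetomin at 5 h and 12 h, 1526 for chaetocin against MeS-chaetocin 5 h, 0 between the MeS compounds at 12 h, and 1306 and 307 for the chaetocin and chetomin time comparisons. With no trend the counts were 4 for MeS-chetomin 5 h, 0 between the MeS compounds at 12 h and 15 for the chetomin time comparison.

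Of the gene lists, 0 passed camera with an estimated correlation in any of the 8 comparisons with vehicle. The rotation test fry, which asks if a list's own genes move, gave 1 and 17 lists for chaetocin and 6 and 7 for chetomin at 5 h and 12 h, and 0 for both MeS compounds at both times. Median-of-ratios scaling left 2 lists for MeS-chaetocin 5 h, and the GC and length correction 1 for MeS-chetomin 5 h.

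Leaving out 1 library leaves an arm with 1, which is assumed to vary like the other groups. The counts against vehicle then ran from 513 to 2023, 609 to 3256, 0 to 56 and 0 to 80 at 5 h for chaetocin, chetomin, MeS-chaetocin and MeS-chetomin. At 12 h they ran from 1628 to 7890 and 880 to 4912 for chaetocin and chetomin, and stayed 0 for both MeS compounds. Chaetocin against chetomin ran from 10 to 186 and 0 to 1514 at 5 h and 12 h, chaetocin against MeS-chaetocin from 148 to 729 and 5492 to 9189, chetomin against MeS-chetomin from 1624 to 6733 and 3366 to 8620, and the MeS compounds from 0 to 504 and 0 to 2164. Time comparisons ran from 250 to 652, 1 to 581, 0 to 1 and 0 to 2, and the shared calls from 416 to 1512 and 836 to 4380. Lists passing ran from 5 to 11, 6 to 11, 1 to 6 and 1 to 4 at 5 h, and 6 to 12, 7 to 10, 2 to 5 and 2 to 4 at 12 h. Each library that moved a count by over 1.5 times stands beside its result in the report.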

Other observations

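Tests chosen only after their result was seen were the comparison of depth for the genes near 0 in vehicle and the range over pairs of libraries in the last paragraph. The correction for GC content and length and the authors' CPM scale were added after the data were seen, and the bounds for the 3 lists of MeS-chetomin were set before the corrected values were seen.

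Genes of cholesterol synthesis, on a list of SREBP2 targets, went both ways at 12 h. IDI1, an enzyme of isoprenoid synthesis, rose from 27.5 ± 8.89 to 318 ± 6.34 with chaetocin and 239 ± 21 with chetomin (SD, n = 2), log2 differences of 3.52 ± 0.22 (adjusted p 0.000422) and 3.11 ± 0.23 (adjusted p 0.000125). INSIG1, which holds SREBP proteins in the endoplasmic reticulum, rose by 2.63 ± 0.16 and 3.06 ± 0.17. Of 20 members 5 rose and 6 fell with chaetocin (5 and 8 adjusted over the list alone; 6 and 4 on the authors' CPM scale), and 3 rose and 9 fell with chetomin (3 and 11; 4 and 4 on the authors' CPM scale). The list did not pass camera in either (adjusted p 0.832 and 0.224). IDI1 lost its call with chetomin when either chetomin replicate was left out (adjusted p 0.0509 and 0.0527).

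Hypoxia genes were split in the same way. SLC2A1, the main glucose transporter of many cells (ENSG00000117394, GRCh38 chromosome 1, 42925375 to 42959176), fell from 275 ± 18.6 to 48.4 ± 5.67 with chaetocin and 61.3 ± 13.1 with chetomin at 12 h (-2.48 ± 0.14, adjusted p 0.000417, and -2.16 ± 0.19, adjusted p 0.000215), while VEGFA rose by 1.40 ± 0.14 with chaetocin and 0.60 with chetomin (adjusted p 0.0324). HIF1A fell by 1.07 ± 0.20 with chaetocin (adjusted p 0.0071) and by 1.19 with chetomin, a call that ended on the authors' CPM scale (-0.41, adjusted p 0.16). With chaetocin 2 of 29 members rose and 9 fell (8 and 5 on the authors' CPM scale), with chetomin 1 rose and 8 fell (3 and 6), and camera passed neither (adjusted p 0.71 and 0.29). VEGFA and HIF1A lost their calls when either treated replicate was left out (adjusted p 0.054 to 0.24). Among autophagy genes MAP1LC3B rose by 1.27 ± 0.15 with chaetocin and 1.39 ± 0.17 with chetomin, and the receptor gene SQSTM1 by 1.41 ± 0.20 and 1.35, in a list with 3 up and 4 down, and 3 up and 2 down, of 18 (camera adjusted p 0.832 and 0.803). Neither gene kept its call when either treated replicate was left out (adjusted p 0.0554 to 0.143).

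Genes near 0 in vehicle at 12 h (under 0.1 in both libraries) and at 1 or more in both treated libraries numbered 264 with chaetocin and 185 with chetomin, 152 of them with both, against 1 with MeS-chaetocin and 0 with MeS-chetomin. All 264 and 185 were also called up, which is no separate support, since the same values picked these genes. Examples, chosen after their values were seen, are MUC5AC, a secreted mucin (ENSG00000215182, GRCh38 chromosome 11, 1157953 to 1201138, 49 exons), at 9.93 ± 0.41 with chaetocin and 14.5 ± 3.64 with chetomin, HTRA3 at 25.3 ± 1.87 and 21.6 ± 0.962, and the immunoglobulin gene IGHA1 at 9.71 ± 0.679 and 24.6 ± 1.23. Their median value was 2.12 with chaetocin and 2.09 with chetomin, and 157 and 104 of them are annotated as protein coding.

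For these genes, deeper sequencing of the treated libraries is argued against, as their mean effective library size was 0.739 times that of vehicle (23.3 against 31.5 M reads). An effective size may hold a scaling factor, so this bears on read totals only if that factor was similar in the groups. A filter on low genes by the authors is argued against too, since it acts on both groups alike and genes gained outnumbered genes lost by at least 88 to 1, with 3 and 1 lost. Read-through from an expressed gene upstream on the same strand may account for part: among the gained genes with an expressed same-strand neighbour within 20 kb on 1 side only, 70.9% had it upstream (56 against 23; exact binomial p 0.000264, 95% interval 59.6 to 80.6), against 47.7% of 1000 drawn genes measured in vehicle (133 against 146, exact binomial p 0.473, interval 41.7 to 53.7). Most of the 297 genes gained with either compound have no such neighbour, and for them read-through is not tested by this share. A response of the cells to the compounds stays open as an untested explanation.

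MeS-chetomin at 5 h shifted the proteasome list by -0.40, histone methyltransferases by 0.41 and histones by -0.35 with no member called. A candidate explanation is a trend of the libraries with transcript length and GC content. After its correction the shifts were -0.14, 0.09 and -0.01 (adjusted p 0.142, 0.626 and 0.839), so that 0 of the 3 lists passed. The correction also removes any response that follows length or GC content, so a response of the cells and a library trend cannot be told apart.

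The last hypothesis is that part of the chaetocin response is present with MeS-chaetocin, since HMOX1, OSGIN1 and WNT16 stand in the authors' deposited table for it at both times. It was tested on genes changed by at least 1 on the log2 scale with chaetocin, as the log2 difference MeS-chaetocin minus MeS-chetomin, which needs no vehicle. At 5 h the median of the 419 higher genes exceeded that of the 652 lower genes by 0.09 (0.04 to 0.13 over the 4 pairs of 1 library from each group; camera p 0.0458 for the higher set, p 0.324 with an estimated correlation, and 0.926 for the lower set), and by 0.04 after the correction for GC content and length. At 12 h the difference was -0.07 (-0.12 to -0.03 over the 4 pairs; camera p 0.5 for 1570 higher genes and 0.135 for 1784 lower genes), where 0 or less had been set as the result if no part is present. This argues against a part larger with MeS-chaetocin than with MeS-chetomin over these genes as a set at 12 h. After the correction for GC content and length, however, the difference was -0.02 (-0.04 to 0). A part present with both analogs would cancel in this contrast, which therefore cannot test its presence. Single genes are not covered either, as HMOX1 was higher by 0.93 at 12 h (adjusted p 0.133, and 0.0461 with a shared spread). The hypothesis stays open at 5 h. At 12 h it stays open for a part present with both analogs, and it may hold for a few genes.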
